A study of Homo sapiens with 95 samples.

How the data were processed

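Human induced pluripotent stem cells (hiPSC) and the cardiac cells derived from them were assayed by droplet single-cell RNA-seq, bulk RNA-seq and ChIP-seq, which sequences DNA bound by a chosen protein. Per the labels, lines were unedited (WT), carried the P496L change in GLYR1, a nuclear protein that binds nucleosomes, or were knockouts (KO) of GLYR1, GATA4, NKX2-5 or TBX5. Cells were differentiated with the small molecules CHIR99021 and IWP4, per the labels' protocols, with the seeding density tuned for each clone. Knockdowns used siRNA against GATA4 (siGATA4) or GLYR1 (siGLYR1) beside a control siRNA (siControl).

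The single-cell files held UMI counts of 16 libraries, which the authors made with Cell Ranger; the submitters' processing notes name version 5.0.1 and the labels' extract protocol version 2.2.0. They are filtered barcode matrices per the file headers and labels, with gene IDs and symbols in the same files. The siGATA4 file held log2 CPM of 6 libraries that the authors had normalised. Its lowest value equals log2 of 0.01, and 2 to the power of the values sums per library to between 954142 and 1054633. Whole reads could be recovered from it within 0.05 of a read. The deposited tables of the siGATA4, knockout and siGLYR1 comparisons held log2 fold changes with p-values and FDR from the authors' tests. For siGATA4 and the knockouts these were likelihood ratio tests, with the likelihood ratio given as a score. Columns 3 to 7 of the siGLYR1 table carry no header, so their meaning was read from the values and their order. Bowtie2 2.2.4, STAR 2.7.3a and FastQC are named in the submitters' processing notes without a role. Domain lists of GLYR1 and H3K36me3, named BCP peaks per the file headers and names, gave start and end on hg19 and no score, 1 list per library. GATA4 binding events came from 2 libraries as windows on hg19 with a deposited score whose scale the files do not name. Counting rules, strand use and peak calling settings are not stated, so genes that overlap an antisense gene, such as ZNF667 and ZNF667-AS1, are uncertain in bulk.

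Cells with at least 2000 detected genes and at most 25% mitochondrial UMIs were kept. The gene minimum had been lower and was raised to the valley of the distribution after the data were seen; using all barcodes is among the alternatives. Kept cells of each stage were clustered with scanpy 1.11.5 on 2000 variable genes scaled within processing batch, 30 principal components, 15 neighbours and Leiden resolution 0.8 (leidenalg 0.10.2). A cluster took a name ending in "-like" from the class with most of its fixed markers when at least 3 of them were 1.5 times higher there and seen in at least 10% of its cells, and it stayed unnamed when its 10 leading genes belonged to another lineage or its depth was low. Scrublet marked 0.39% of 32307 cells, so the caller had not worked; removing the 910 cells with the highest doublet scores was added as an alternative. Free RNA was not corrected for.

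UMI counts were summed per library over all kept cells (whole-library sums) and over cardiac-like cells. They were tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test, Benjamini-Hochberg adjustment) in 1 fit of the 10 day 6 and day 18 libraries whose labels agree, with processing batch within stage. The fits covered 21872 and 17423 genes, with 3 residual degrees of freedom in each. Each day 6 batch held 1 WT and 1 P496L library. For 2 day 18 libraries, the title words and the bracketed library name give opposite genotypes, and these 2 were left out of the day 18 comparisons; fits by title and by library name are alternatives. The 24 gene lists were tested with limma 3.58.1: camera with a preset and with an estimated correlation, and fry. Genes are called at an adjusted p under 0.05. CPM beside these tests use TMM-scaled library sizes, while levels by stage and at day 0 use plain library totals.

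siGATA4 and siControl, 3 libraries each, were compared with limma (eBayes with trend) on the log2 CPM of 25380 genes, since the values are not counts. Same-numbered siGATA4 and siControl libraries had correlations across genes of 0.185, 0.105 and 0.324, and differently numbered ones -0.268 to 0.144. The replicate numbers may therefore pair these samples, but the ranges overlap and the labels do not say what a number shares. The fit with the replicate block is an alternative. Single-cell replicate numbers do not pair libraries: same-batch day 6 pairs of whole-library sums correlated at 0.351 to 0.656 and the same-numbered pairs of different batches at -0.406 and -0.138. Replicates' p-values measure the spread between samples, which may be technical. The knockout table gives 1 FDR per gene for all 3 knockouts together, so its fold changes per knockout are descriptive. Per-library knockout values were not used here, and chance correlation from the shared WT libraries could not be simulated. Of the file columns, 6 were not used.

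For hiPSC, where a genotype has 1 library, the ratio of CPM is given with a 95% exact conditional binomial interval for counting error, over genes with at least 100 UMIs in both libraries together. Gene lists are placed by the percentile of their median among 10000 random lists of the same size and similar expression. ChIP domains were merged across libraries; a region separates 2 groups when every library of one and no library of the other has a domain in it. Covered length was compared by exact two-sided permutation tests. Overlap of bases or events was set against 100 circular shifts along each chromosome, over the span to its last domain, with gaps not excluded. GATA4 events were set against bases that GLYR1 domains covered in at least 3 of the 5 WT progenitor libraries. ChIP of TBX5, NKX2-5, MEIS1 and ISL1, and inputs, were not used here.

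Genes named were chosen by a rule: the targeted gene, up to 4 members of each list with the largest absolute change at an adjusted p under 0.05, and the 6 largest rises and 6 largest falls with mean log2 CPM above 1 that moved the same way in every batch pair or whose group ranges do not overlap. For authors' tables the last condition was dropped. For the 2-library comparisons the 6 largest and smallest ratios and list members past 1 on the log2 scale were eligible, and for regions the 3 widest. Tests, gene lists, markers, this rule and most alternatives were fixed before the data were examined. The alternatives covered normalisation, filters, test, batch term, replicate block, depth, clustering, label reading and leaving out each library.

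The steps were tested on simulated data with 200 changed genes. In simulated whole-library sums, edgeR recovered 35.4%, 77.4% and 98.4% of genes changed by log2 1, 2 and 4 at day 6 and 16.9%, 69.4% and 100% at day 18, with 4 and 6 unchanged genes called among 21517. In cardiac-like sums of 17063 genes it recovered 58.8%, 90.9% and 100% at day 6 and 39.7%, 75.8% and 95.2% at day 18. These counts were drawn with the dispersion trend of the real fit and no spread of genes around it. Recovery and false calls in the real sums can therefore differ. For siGATA4, limma recovered 86% and 99% at log2 1 and 2, with 12 unchanged genes called among 25380. The intervals held the true ratio for 95.45% of 15901 simulated genes. Other tools were DESeq2 1.42.0, statmod 1.5.0, R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.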

Results

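The series compared cells that differ in GLYR1 or in cardiac transcription factors while human iPSC become cardiac cells. Of its 95 samples, 16 were single-cell libraries, at day 0 (hiPSC), day 6 (cardiac progenitors) and day 18 of differentiation. At day 0 there were 2 WT, 1 P496L and 1 GLYR1 KO library, and at days 6 and 18 there were 3 WT and 3 P496L libraries each by title. Day 0 libraries kept 1570 to 2395 cells and 103748977 to 122085198 UMIs. Day 6 libraries kept 1296 to 4493 cells and 59467860 to 122185575 UMIs, and day 18 libraries kept 1252 to 2020 cells and 34947894 to 56771284 UMIs. Bulk RNA-seq covered 3 siGATA4 and 3 siControl libraries at day 7, with 28671481 to 30574989 reads recovered per library, and deposited comparisons of 3 knockouts at day 6 and of siGLYR1. For the deposited comparisons the depth is unknown. GLYR1 ChIP-seq covered 17 libraries, beside 4 of H3K36me3, a histone mark of transcribed gene bodies, and 2 of GATA4.

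In WT libraries, the pluripotency gene POU5F1 went down over the 3 stages while TNNT2, MYL7, NKX2-5 and TBX5 went up (CPM of plain library totals). POU5F1, a core pluripotency factor, was at 996 ± 226 CPM at day 0 (SD, n = 2), 15.3 CPM at day 6 (n = 3) and 0.301 CPM at day 18 (n = 2). TNNT2, cardiac troponin T, was at 5.87 CPM, 1179 ± 801 CPM and 2984 ± 51.4 CPM at these stages, and MYL7, the atrial myosin light chain, at 0.971, 2094 and 14880 CPM. NKX2-5, an early cardiac transcription factor, went from 0.318 CPM to 76.5 ± 46.0 and 241 CPM, and TBX5 from 0.0632 to 9.32 and 42.7 CPM. ISL1, a factor of heart progenitors, was at 57.4 CPM at day 6 and 20.9 CPM at day 18. GLYR1 itself was at 70.3 ± 22.3, 57.3 ± 7.72 and 29.8 ± 4.94 CPM. No test was run between stages, because each stage is also its own set of cultures.

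Does the P496L change alter the cells of the differentiation? Cardiac-like cells made up 16.96% ± 12.3 of P496L libraries and 41.47% ± 21.6 of WT libraries at day 6 (SD, n = 3 each; exact permutation p = 0.2, two-sided). P496L was lower in each of the 3 batches, by -20.99, -37.09 and -15.45 percentage points. At day 18 the shares were 21.32% ± 11.4 in P496L and 69.0% ± 3.59 in WT (n = 2 each), and the differences in the 2 batches were -37.09 and -58.27 points. The exact permutation p of 0.333 is the smallest that 2 against 2 libraries allow. Neither difference passed the test, and at day 6 the smallest possible p is 0.1. The permutation test does not use the batch pairs. The labels name no other P496L clone, and seeding density was tuned for each clone. An effect of the P496L change on these shares therefore cannot be told apart from clone or seeding. Neural or ectoderm-like cells made up 24.31% ± 22.7 of P496L and 3.56% ± 4.99 of WT cells at day 6, and 16.24% and 0.07% at day 18. Endoderm-like cells stood at 23.82% and 18.99% at day 6 and at 8.86% and 1.58% at day 18, in P496L and WT. Their difference changed sign between batches, with -9.91, 21.7 and 2.7 points at day 6 and 15.09 and -0.53 points at day 18. Fibroblast-like cells stood at 3.83% and 0.56%, then at 22.27% and 18.4%. Epicardial-like cells, which were named only at day 18, made up 1.28% of P496L and 5.06% of WT cells. Endothelial-like cells averaged at or under 1.27% in both genotypes. Clusters without a name held 30.05% ± 29.4 and 34.15% ± 18.0 of cells at day 6, and 29.62% and 5.6% at day 18. In the day 6 batch with the cardiac-like difference of -15.45 points, they held 64.0% of P496L and 54.53% of WT cells. Without WT replicate 1 the day 6 difference was -12.25 points, and without scaling within batch, a setting added after the data were seen, -10.06 points.

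**Figure D1:**
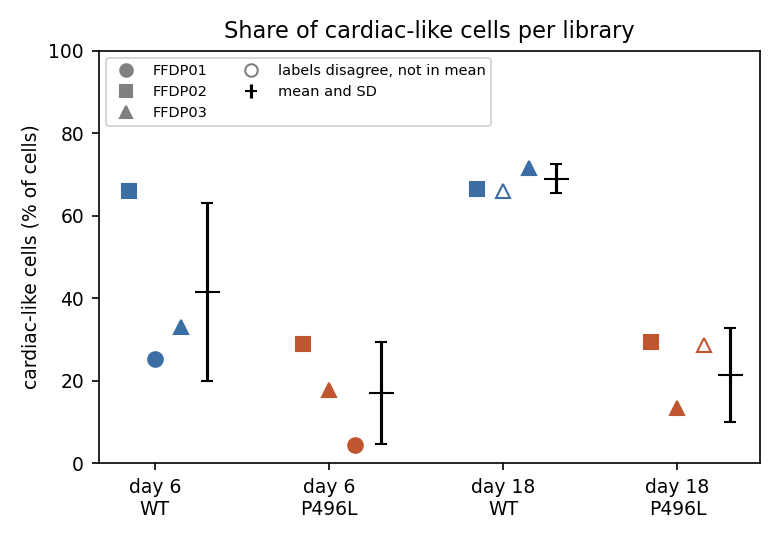
Cardiac-like cells as a percentage of all kept cells (vertical axis) in each WT and P496L library at days 6 and 18, with 1 point per library, its batch shown by the symbol, and the mean with SD. At day 18 the WT mean is 69.0% and the P496L mean 21.32%; open symbols are the 2 libraries whose labels disagree.

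In whole-library sums at day 6, a small set of genes differed strongly between P496L and WT. GLYR1 (ENSG00000140632) was at 63.3 ± 15.9 CPM in P496L and 56.3 ± 9.78 CPM in WT (TMM-scaled, as are the CPM of all these tests), a log2 fold change of 0.16 (SE 0.11, edgeR adjusted p = 0.615, n = 3 each). ANXA1, a phospholipid-binding protein, rose by 2.59 (SE 0.23, adjusted p = 0.03), from 16.0 ± 12.0 to 85.5 ± 42.9 CPM. POSTN, a matrix protein of mesenchymal cells, rose by 2.27 (adjusted p = 0.0228), and IFI6 and COTL1 rose by 1.58 and 1.45. Among genes with mean log2 CPM above 1, the largest falls were the linker histone gene HIST1H1A (-7.89, SE 0.37, adjusted p = 0.0203) and the zinc finger genes ZNF667 (-6.55, SE 0.43) and ZNF471 (-4.55). ZNF667-AS1, which lies antisense to ZNF667, fell by 5.91, CCDC125 by 4.95 and ZNF528-AS1 by 3.67. edgeR called 26 genes, 4 higher and 22 lower, and 2703 of 21872 had an unadjusted p under 0.05. DESeq2 called 915. The count rests on every day 6 library: without any 1 of them edgeR called 0 or 1 gene, and without 1 day 18 library of the same fit it called 322 to 369.

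Cardiac gene groups were lower in P496L at day 6 as lists, with no member called over all genes. The sarcomere list, the contractile apparatus, had a median log2 fold change of -2.05, and 19 of its 24 genes fell when adjusted over the list alone (camera FDR = 5.39e-32). That call was lost with an estimated correlation (p = 0.0599). Cardiac transcription factors (median -0.76, 11 of 18 lower when adjusted over the list alone) had p = 0.0483 with an estimated correlation, which is 0.531 after adjustment over the 24 lists. The 15 calcium handling genes (median -0.81, 7 lower when adjusted over the list alone) had p = 0.0822 with an estimated correlation. The share of cardiac-like cells, given above, moved the same way. Of the fibroblast and matrix list, POSTN was the member called.

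At day 18, cardiac transcription factors, glycolysis, matrix and neural genes were among those called in whole-library sums. These calls rest on the spread of the fit shared with day 6. All were lost with day 18 fitted alone, or when any day 6 library was left out of that fit. NKX2-5 fell by 1.85 (SE 0.34, edgeR adjusted p = 0.0476), from 258 ± 38.7 to 74.0 ± 27.7 CPM (n = 2 each). GATA4 fell by 1.33 (SE 0.25, adjusted p = 0.0478), from 74.7 to 32.4 CPM, and TBX20 and GATA5 fell by 1.54 and 1.26, so that 4 of the 5 cardiac transcription factors called, of 18 measured, are named here. TNNI3, cardiac troponin I, fell by 1.92 (adjusted p = 0.0449), from 234 to 67.9 CPM, as the only sarcomere gene called. Of calcium handling genes, CACNB2 fell by 1.54 and ASPH by 0.91. GLYR1 differed by 0.13 (SE 0.13, adjusted p = 0.56). Of 13 glycolysis genes 9 fell, among them SLC2A1 by 1.32, LDHA by 1.31, GPI by 1.17 and PGK1 by 1.13 (camera FDR = 3.66e-12; p = 0.067 with an estimated correlation). Of 15 neural and ectoderm genes, OTX2, TUBB3 and STMN2 rose by 3.29, 3.09 and 2.92, and the list's median was 3.79 (camera FDR = 1.27e-07; p = 0.154 with an estimated correlation). Neural or ectoderm-like cells were at 16.24% in P496L against 0.07% in WT at day 18, and cardiac-like cells at 21.32% against 69.0%. BGN, POSTN and COL1A2 of the fibroblast and matrix list rose by 2.55, 1.80 and 0.85, and 7 of its 15 genes did when adjusted over the list alone. Of 12 epicardial genes, TBX18 fell by 1.93 and BNC1 by 1.45. BMP and TGF-beta targets moved both ways, CCN2 (1.64) and ID1 (1.36) up and BMPER (-1.87) and BMP2 (-0.95) down.

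Other lists had fewer called members at day 18. The second heart field and progenitor list gave LGR5 (3.56), the oxidative metabolism list LPL (2.37), and the endothelial list CLDN5 (7.23) and ERG (2.37). GSC (4.19), NKD1 (2.57), DPPA4 (2.36), PTPRC (4.64) and NOTCH3 (1.20) were the single rises of the early mesoderm, WNT, pluripotency, blood and smooth muscle lists, and DES (-1.62) fell in the last. The cell cycle lists gave CDT1 (0.88) and CCNB2 (1.13), and 17 of 18 G2M genes rose when adjusted over the list alone, with p = 0.181 with an estimated correlation. HSPA1A, a heat shock protein, fell by 4.41 (adjusted p = 0.0387). SOST rose by 7.61 (SE 0.68, adjusted p = 0.0304), from 0.654 to 128 CPM, and CDC20B, C1orf194 and SPAG6, genes of multiciliated cells, rose by 7.78, 6.79 and 6.29. SLC15A4 had 401 UMIs in WT and 0 in P496L, and HIST1H1A 81 and 0. ZNF667 fell by 6.68. edgeR called 830 genes, 467 higher and 363 lower, with 5833 at an unadjusted p under 0.05, and DESeq2 called 3459. The count was 0 without any 1 day 6 library of the shared fit, 0 with day 18 fitted alone, and 474 to 2229 without 1 day 18 library.

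Whether the P496L effect differs between the stages was tested in the same fit. edgeR called 0 genes for the day 18 minus day 6 difference, with 3223 at an unadjusted p under 0.05, while DESeq2, added after the data were seen, called 954. The sarcomere list had a median difference of 0.63 with p = 0.624 with an estimated correlation. Glycolysis genes had a median difference of -0.86 with p = 0.105 with an estimated correlation, and G2M genes one of 0.87 with p = 0.189 with an estimated correlation. Without 1 day 18 library the edgeR count was 196 to 319.

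Sums over cardiac-like cells ask what differs within that class, whose markers include 12 of the 24 sarcomere genes. At day 6, TNNI3 fell by 1.92 (SE 0.31, edgeR adjusted p = 0.0362) and was the sarcomere gene called, while 17 of the 24 fell when adjusted over the list alone (median -0.92; camera FDR = 1.91e-15; p = 0.129 with an estimated correlation). EYA1, a progenitor gene, rose by 2.23 and L1TD1, a pluripotency gene, fell by 2.71 (SE 0.29, adjusted p = 0.00844). The matrix genes POSTN and BGN rose by 4.55 (SE 0.51) and 2.93. ANXA1 rose by 2.96 (SE 0.27, adjusted p = 0.00443), NPR3, a natriuretic peptide receptor, by 2.52, DTNA by 2.42 and CST1 by 2.41. HSPA1A fell by 4.34 and ZNF667 by 6.68 (SE 0.28, adjusted p = 7.49e-05). HIST1H1A had 514 UMIs in WT and 0 in P496L, SLC15A4 434 and 0, and AC112178.1 263 and 0. GLYR1 differed by 0.12 (adjusted p = 0.773). edgeR called 122 genes, 39 higher and 83 lower, with 2157 of 17423 at an unadjusted p under 0.05. Leaving out 1 library gave 7 to 383 calls, with 7 and 8 without WT replicate 2 and P496L replicate 3 of day 6. In P496L replicate 2, cluster 6 held 53.3% of the cardiac-like cells, and 42.72% of its cardiac-like cells had at least 2 TNNT2 UMIs against 80.0% to 95.78% in the other day 6 libraries (endoderm-like cells 6.09% against 5.2% to 25.13%).

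Within cardiac-like cells at day 18, CCN2, ANXA1 and PDLIM3 were among the genes that rose in P496L, and no gene of the sarcomere list was called. CCN2, a matricellular target of TGF-beta signalling, rose by 2.37 (SE 0.26, edgeR adjusted p = 0.0193), ANXA1 by 2.46, FAM171B by 2.36, BANCR by 2.35 and GABRB2 by 2.26. PDLIM3, a protein of the sarcomere's Z-disc, rose by 2.29 (SE 0.27, adjusted p = 0.0208). ZNF667 fell by 7.09 (SE 0.34, adjusted p = 0.000135), and HSPA1A had 333 UMIs in WT and 0 in P496L, AC112178.1 312 and 0, SLC15A4 265 and 0 and PAX8-AS1 139 and 0. The sarcomere list had a median of 0.20, with p = 0.645 with an estimated correlation. The fibroblast and matrix list had a median of 1.10 with 7 members higher when adjusted over the list alone (camera FDR = 1.62e-11; p = 0.0123 with an estimated correlation). Natriuretic and stress-responsive genes had p = 0.0349 with an estimated correlation, and no list passed after adjustment with that correlation, the lowest FDR being 0.296. GLYR1 differed by 0.08 (adjusted p = 0.911). edgeR called 45 genes, 20 higher and 25 lower, with 1744 at an unadjusted p under 0.05, and 4 to 164 when 1 library was left out. WT replicate 1 held 72.3% of its cardiac-like cells in cluster 4, which held 0.1% of those of WT replicate 3. Cluster 6 held 46.3% and 14.8% of the cardiac-like cells of P496L replicates 1 and 2, against 0.6% and 3.4% in WT replicates 1 and 3.

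At day 0 the P496L hiPSC library resembled the WT library of its batch, apart from a short list of genes. There is 1 library per genotype, so these values have no replicate check. GLYR1 was at 96.3 CPM in P496L and 86.0 CPM in WT. Of 15502 genes, 76 had a log2 ratio over 1 and 186 under -1, while the 2 WT libraries, of different batches, gave 667 and 2011 of 15882. The largest ratios were LINC01972 (4.08), ANKRD62 (4.05), GOLGA8R (3.7), TBX15 (3.56), PAX7 (2.64) and ZIC1 (2.41), the last 3 being developmental transcription factors. SLC15A4 had 0 UMIs in P496L and was at 5.36 CPM in WT. CCDC125 had a ratio of -7.38 (95% interval -8.60 to -6.40), AC112178.1 one of -7.72 (-8.94 to -6.74) and ZNF492 one of -7.44 (-9.72 to -5.88). The p53 target list had a median of -0.26, at percentile 0.01 of random lists, and of -1.42 between the 2 WT libraries. Cardiac transcription factors (6 genes) had a median of 0.561 at percentile 99.99. Sarcomere and endothelial genes (9 each) had medians of -0.357 and -0.461, at percentiles 0.03 and 0.14. Between the 2 WT libraries these 3 lists were at -0.095, -0.15 and -0.006, at percentiles 82.97, 69.49 and 95.98.

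The library labelled GLYR1 knockout hiPSC differed from its WT library across much of the transcriptome. Its GLYR1 level was 22.3 CPM (95% interval 21.4 to 23.2) against 54.5 CPM, a log2 ratio of -1.29. WT replicates 1 and 3 of day 18 were at 33.25 and 26.27 CPM. A 3' tag outside a deleted part would not report a deletion, and the labels do not place the edit. POU5F1 had 5 UMIs in the library labelled knockout and 119962 in its WT library, NANOG 14 and 6981, and SOX2 192 and 34313. The pluripotency list had a median of -9.15, at percentile 0 of random lists. COL3A1, DCN, LUM and NNMT, the first 3 being matrix genes of fibroblasts, had 94021, 109437, 46341 and 35346 UMIs there and 0 in WT. COL1A1 had a log2 ratio of 6.46, and the fibroblast and matrix list a median of 6.46, at percentile 100. CDKN1A, a p53 target that slows division, had a ratio of 4.97, while all 18 G2M genes lay under -1 (median -3.89). Of 16603 genes, 3571 lay over 1 and 4713 under -1. One label field of this library names the P496L genotype, so it is described only as labelled.

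Knockdown of GATA4, a zinc finger factor of the early heart, lowered cardiac and endodermal genes in day 7 cells. GATA4 (ENSG00000136574) itself fell by 2.20 (SE 0.09, limma adjusted p = 4.83e-13), from 6.64 ± 0.11 to 4.44 ± 0.13 log2 CPM (SD, n = 3 each). TBX5, a partner in cardiac gene activation, fell by 2.33 (adjusted p = 1.18e-11), IRX4, a ventricular factor, by 1.81 and GATA5 by 0.97, and of 18 cardiac transcription factors 11 fell and 2 rose (camera FDR = 3.27e-05; p = 0.0363 with an estimated correlation, 0.218 after adjustment, so that call was lost). Of 22 sarcomere genes 16 fell and 2 rose, with MYBPC3 at -1.43, MYOZ2 at -1.32, TNNI1 at -1.0 and MYL3 at -0.99 (camera FDR = 1.65e-09, lost with p = 0.0156 with an estimated correlation, 0.184 after adjustment). Of 16 endoderm genes 12 fell and 2 rose, with APOA1 at -4.37 (adjusted p = 5.58e-14) and FGB at -3.78 (adjusted p = 4.62e-14), both secreted by liver-type cells, and CER1 at 3.67 (camera FDR = 1.65e-09, lost with p = 0.00732 with an estimated correlation, 0.176 after adjustment). GLYR1 differed by -0.23 (SE 0.10, adjusted p = 0.13). limma called 5699 genes, 2746 higher and 2953 lower.

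Other gene groups moved in both directions under siGATA4. Calcium handling gave 6 falls and 1 rise of 15, among them RYR2 (-0.89), CACNB2 (-0.89) and TRDN (-0.75) against FKBP1B (0.58), with p = 0.109 with an estimated correlation. Oxidative metabolism gave 6 falls and 1 rise of 16, ACSL1 (-1.20) and PPARGC1A (-0.94) against LPL (1.41), with p = 0.0911 with an estimated correlation. Of 12 unfolded protein response genes 7 rose and none fell, with CHAC1 at 1.70, ASNS at 1.5 and TRIB3 at 1.16 (p = 0.0623 with an estimated correlation). Of 11 smooth muscle genes 5 rose and 1 fell, with MYH11 at 0.93, TAGLN at 0.90 and ACTA2 at 0.71 (p = 0.0231 with an estimated correlation, 0.184 after adjustment). Heat shock and immediate early genes gave 8 rises and 3 falls of 14 (FOSB 2.08, FOS 0.88; p = 0.155 with an estimated correlation), and G2M genes 7 rises and 1 fall of 18 (p = 0.309 with an estimated correlation). The second heart field and progenitor list gave 6 rises and 3 falls of 18, with HOXB2 (1.29), CXCR4 (1.38) and EYA1 (1.0) among the rises (p = 0.0928 with an estimated correlation). No list passed the adjustment over 24 lists in camera with an estimated correlation, the lowest FDR being 0.176. With fry, which does not set a list against other genes, several lists passed. The sarcomere, endoderm and cardiac transcription factor lists had fry FDRs of 0.0039, 0.0014 and 0.0014. Others did not pass, such as glycolysis (fry FDR = 0.27) and blood (fry FDR = 0.97).

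The remaining lists were mixed under siGATA4. WNT targets gave 3 rises and 6 falls of 13, with SP8 at -4.53, SP5 at -2.52 and AXIN2 at -0.75. Early mesoderm genes gave 2 of each among 5, EOMES at -2.74 and LEFTY2 at 2.79, and pluripotency genes 4 rises and 6 falls of 15, SOX2 at 1.41 and TDGF1 at -1.36. BMP and TGF-beta targets gave 5 rises and 3 falls of 13, with CCN2 at 1.15, and fibroblast and matrix genes 6 and 3 of 15, with COL1A1 at 1.29, PDGFRB at 1.30 and FN1 at -1.09. The fibroblast median was -0.11 while the direction of its camera test was up, and that test did not pass (FDR = 0.266). Glycolysis gave 2 rises and 5 falls of 13 (LDHA 0.81, GPI -0.53), endothelial genes 1 and 4 of 15, epicardial genes 3 and 2 of 11 (BNC1 1.04, LRP2 -1.48), neural and ectoderm genes 1 and 2 of 12 (MAP2 1.62), and blood genes 1 and 2 of 6 (HBE1 -2.78). The p53 targets gave 5 rises and 1 fall of 13 (CDKN1A 0.94, MDM2 0.45), S phase genes 3 and 1 of 17, natriuretic genes 2 and 1 of 7, and GLYR1-related chromatin genes 1 and 2 of 11 (KDM1B 0.41, DNMT3A -0.63). Among genes with mean log2 CPM above 1, the largest rises were DIO2 (3.6, adjusted p = 5.22e-12), SST (3.56), ANGPT2 (3.52), CBLN2 (3.29), PGR (3.07) and ITGA2 (2.88). Beside the apolipoprotein and fibrinogen genes the largest falls among these were RFX6 (-3.94), DPP4 (-3.86, adjusted p = 3.99e-15) and CUBN (-3.80), genes of gut, islet and kidney epithelia.

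**Figure D2:**
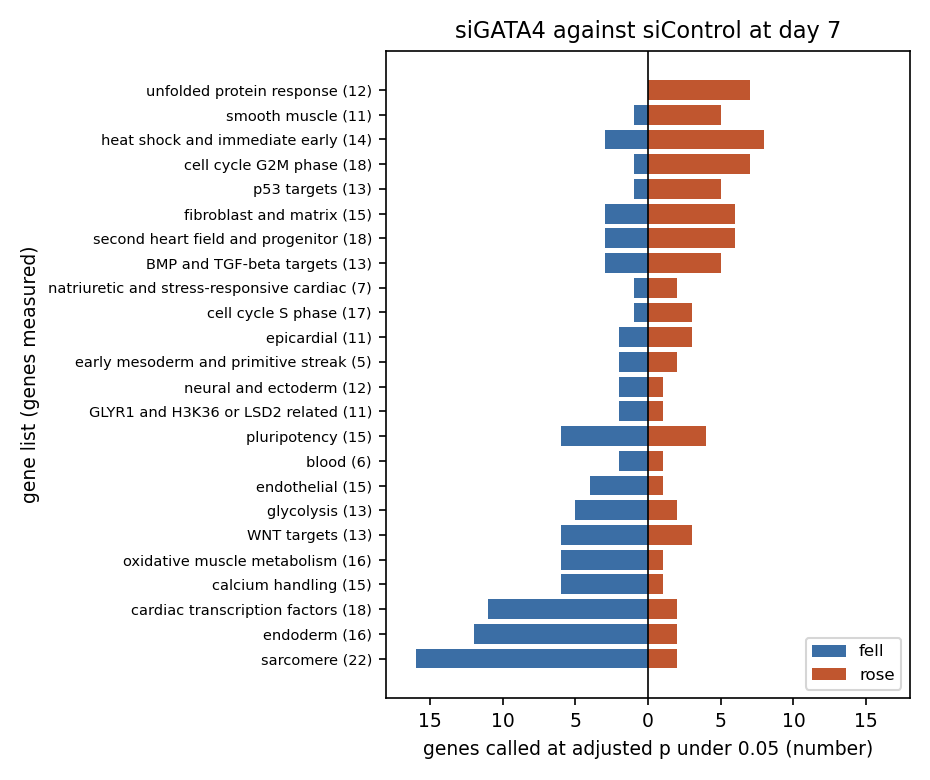
Number of genes of each list (vertical axis, with the number measured) that rose or fell under siGATA4 against siControl at an adjusted p under 0.05 (horizontal axis, number of genes; n = 3 libraries each). The sarcomere bar reaches 16 falls and the endoderm bar 12 falls.

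The deposited knockout table compares loss of GATA4, NKX2-5 or TBX5 with WT at day 6, all 3 being core cardiac transcription factors. GATA4 itself had a log2 fold change of -2.23 in its knockout, NKX2-5 -0.47 in its own and TBX5 -3.09 in its own. An edited transcript can still be counted, so these values check the labels only in part. Of 22 sarcomere genes, 21, 20 and 21 were lower in the GATA4, NKX2-5 and TBX5 knockouts at the authors' FDR under 0.05, which is joint for the 3. MYL3 stood at -3.03, -2.60 and -3.54, TTN at -2.66 and MYBPC3 at -2.66 in the GATA4 knockout, and NPPA, an atrial natriuretic peptide, at -3.34 and -4.91 in the NKX2-5 and TBX5 knockouts. TBX5 was at -3.45 in the GATA4 knockout and NKX2-5 at -4.19 in the TBX5 knockout. Endoderm genes were higher for 15 of 16 in the NKX2-5 and TBX5 knockouts, with RBP4 at 5.65 in both and TTR at 4.01 and 4.25, and for 7 of 16 in the GATA4 knockout. Endothelial genes were higher for 9 of 16 in the NKX2-5 and TBX5 knockouts and 4 of 16 in the GATA4 knockout. G2M genes were higher for all 18 in the GATA4 knockout and for 3 and 1 in the others. Of p53 targets 13 of 13 were higher in the GATA4 knockout, with GDF15 at 1.66 and CDKN1A at 1.39, and 2 and 3 in the others. TBX18, an epicardial factor, stood at -5.41 and -7.40 in the GATA4 and TBX5 knockouts, and DCN at -4.07, -5.49 and -6.03.

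Among the largest falls in the NKX2-5 knockout were the zinc finger genes ZFP28 (-6.82), ZNF71 (-6.26), ZNF471 (-5.77), ZNF667 (-5.73) and ZNF470 (-5.42), in the TBX5 knockout PPP1R14C (-6.62), SYNPO2 (-6.23) and ZNF558 (-5.60), and in the GATA4 knockout VCAM1 (-6.26) and HIST1H1A (-6.25). The table puts 21631 of 32625 genes under an FDR of 0.05, which covers the 3 knockouts together and assigns no gene to 1 of them. Across genes, which are not independent replicates, fold changes of the NKX2-5 and TBX5 knockouts had r = 0.902, and those of the GATA4 knockout had r = 0.345 and 0.422 with these. The shared WT libraries add to these correlations by an amount that could not be computed here. Some descriptions repeat a preparation name, so some replicates share a preparation by name. Descriptions of TBX5 knockout replicates 1 and 2 carry a library name of the GATA4 knockout, so the labels of these 2 disagree, which bears on the TBX5 knockout values and their r with the GATA4 knockout.

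Genes called under siGATA4 overlapped those at the knockout table's FDR, which is joint for 3 knockouts and so not specific to GATA4; the controls are separate. Of 25112 genes in both tables, 4718 passed in both against 4057 by chance (odds ratio 2.3, 95% interval 2.13 to 2.48, Fisher's exact p = 9.6e-116, two-sided; genes are not independent). By the fold change of the GATA4 knockout, 68.1% of these had the same sign, 1481 lower in both against 944.7 by chance and 1733 higher in both against 1076.3. DIO2 and SST, among the largest rises under siGATA4, stood at 3.85 and 3.55 in the knockout. EYA1, higher under siGATA4, was at 2.18 there.

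The deposited siGLYR1 table lists 26 genes chosen by the authors, so its directions are no independent evidence about other genes. GLYR1 was lower by log2 -1.51 (the authors' FDR = 2.38e-30, 2 libraries each). The muscle genes TNNI1 (-0.58), TTN (-0.35, FDR = 0.000894) and MYL4 (-0.35) and the cardiac factor GATA6 (-0.40, FDR = 0.00122) were lower, as were VCAN (-0.47) and LAMA1 (-0.37), which build matrix. GATA4 stood at -0.25 with an FDR of 0.11. MYOCD, a coactivator of muscle genes, was higher by 1.11 (FDR = 9.33e-18), as were ADAM19 (0.53) and ANTXR1 (0.48), and MEF2C stood at 0.31 with an FDR of 0.0551.

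GLYR1 domains were broad, and those called covered more of the genome in libraries of cardiac progenitors than in those of hiPSC. Domains covered 166.7 ± 26.3 Mb in 5 WT progenitor libraries and 99.0 ± 34.4 Mb in 6 hiPSC libraries, a difference of 67.7 Mb (exact permutation p = 0.0065, two-sided). The hiPSC libraries ran from 36.15 to 133.7 Mb. The domain lists give neither read depth nor enrichment, on which called length can depend, so a difference in occupancy itself was not separated from these. Of 8093 merged regions, 334 had a domain in every progenitor and no hiPSC library, and 42 the reverse. The widest progenitor regions lie on chromosome 9 from 20694400 to 21012399, chromosome 10 from 61794200 to 62039999 and chromosome 15 from 72114600 to 72341599 (hg19), and the widest hiPSC region on chromosome 2 from 241656600 to 241716799. No hg19 annotation was at hand, so genes are not given for these regions. Within Batch3 the difference was 72.8 Mb (1 progenitor against 4 hiPSC libraries; exact permutation p = 0.2, the smallest possible) and among libraries with no batch label 94.3 Mb (3 against 2; exact permutation p = 0.1, the smallest possible). Separating regions numbered 2605 and 1069 there, with fewer libraries to fulfil the condition, and 680 without progenitor replicate 3.

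P496L progenitors had 100.4 ± 36.8 Mb of GLYR1 domains (n = 3) and WT progenitors of the same set 140.2 ± 29.0 Mb (n = 4). The difference of -39.9 Mb did not pass the test (exact permutation p = 0.257, two-sided) and was -18.7 Mb without P496L replicate 1, which covered 58.1 Mb. Of 7325 regions, 71 had a domain in every WT and no P496L library, the widest on chromosome 15 from 62941400 to 63133199, chromosome 14 from 76128800 to 76307399 and chromosome 5 from 88014000 to 88152399 (hg19). The reverse held for 1 region, on chromosome 8 from 43838400 to 43838999. The total of 72 regions was 170 without P496L replicate 3, 130 without WT replicate 5 and 147 without WT replicate 6. A source label of these P496L libraries says WT while title and treatment say P496L. The share of cardiac-like cells in these ChIP cultures is not known.

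**Figure D3:**
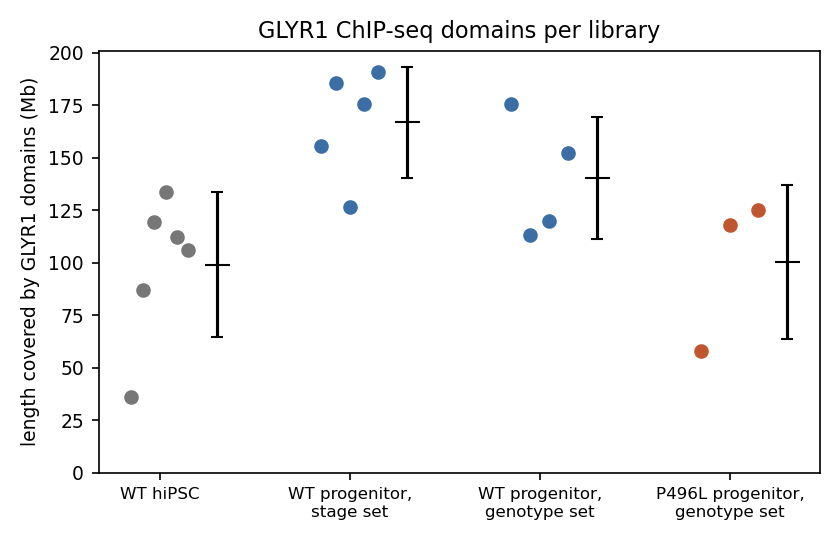
Length covered by GLYR1 domains in Mb (vertical axis) for each ChIP-seq library of WT hiPSC, WT progenitors of the stage and genotype sets and P496L progenitors, with 1 point per library and the mean with SD. WT progenitors of the stage set average 166.7 Mb and hiPSC 99.0 Mb; 1 WT library belongs to both progenitor sets.

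GLYR1 domains lay almost wholly inside H3K36me3 domains of the same stage. In 17 libraries 98.33% ± 0.35 of their bases did, against 14.4% after circular shifts, a fold of 6.95 ± 0.90. The fold was 8.13 ± 0.06 in hiPSC, 6.34 in WT progenitors of the stage set and 6.26 in P496L progenitors. H3K36me3 covered 462.0 Mb in progenitors and 355.8 Mb in hiPSC. GATA4 binding events were slightly depleted in GLYR1 domains: 4.81% of 31660 and 3.90% of 7974 events lay inside, against 5.53% and 5.57% after shifts, folds of 0.87 and 0.70. All 100 shifts gave at least the observed share in both libraries. With bases of any GLYR1 library the folds were 0.972 and 0.882 and 89 and 100 of 100 shifts did, so the larger set's value then lay within the shifts. GATA4 events were at 1.07 and 1.08 times the shifted share in H3K36me3 domains as a whole, a comparison chosen after the data were seen. The shifts can move domains into gaps, where no event can lie, and this raises folds. Values this near 1 therefore show no clear excess.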

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

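The tests of explanations and the counts of other splits in this part were chosen only after the results were seen. Among 15 pairs of a group and a measure, GLYR1 ChIP library 5 of the WT progenitor stage set stood apart with 97.81% of its covered bases inside H3K36me3 domains, where the other 4 had 98.56% to 98.78%. The hiPSC GLYR1 library 1 stood apart with a median domain width of 11.2 kb, where the others had 13.4 to 14.4 kb. Chance puts about 1 in 20 such pairs apart. HMX1, a homeobox factor, was lower in P496L in each batch at day 6 (-3.65) and higher in each at day 18 (2.32), both called by edgeR, and the difference of 5.97 had an edgeR adjusted p of 0.0963, so it did not pass the test of the difference itself. In the library titled P496L replicate 3 at day 18, whose labels disagree and which the comparisons leave out, neural or ectoderm-like cells made up 34.68%, where day 18 libraries with agreeing labels had 28.6% and 3.88% in P496L and at most 0.14% in WT.

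The 22 genes called lower in P496L at day 6, HIST1H1A, ZNF667 and CCDC125 among them, had a median of -2.7 in the single day 0 pair and -2.59 at day 18, with exceptions in HMX1 (2.32 at day 18), INPP5F (-0.42 at day 18, edgeR adjusted p = 0.201) and SLC16A3, EMC10, UNC5B and TNFSF9 (0.12, 0.13, 0.26 and -0.47 at day 0). Fewer cardiac-like cells are excluded as the whole cause, since the median within cardiac-like cells was -3.58 and no batch median lay above -3.18. A difference between edited clones that other edited lines share stays open. Of the set, 31.6% (6 of 19) lay below -2 in at least 1 deposited knockout comparison, against 2.2% of 15848 other genes. That explanation came from the same values, however, and 4 of the 6 (ZNF667, ZNF667-AS1, ZFP28 and ZNF471) were so in the NKX2-5 knockout alone. Several genes of the set are also neighbours, and ZNF667-AS1 lies antisense to ZNF667, so they do not count as independent genes. Under siGATA4, where no clone differs, 0 of 18 lay below -2 and the lowest was -1.08. The share of all genes below -2 under siGATA4 was not computed, so this count cannot decide on a clone difference. An effect of the P496L change cannot be told apart from the clone, because the labels name no other P496L clone.

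The sarcomere list had a median of -2.05 at day 6 and -1.38 at day 18 in P496L whole-library sums, with p = 0.0599 and 0.253 with an estimated correlation, and TNNI3 at day 18 was the only member called by edgeR. At day 18 the log2 ratio of the cardiac-like shares was -1.69 and the sarcomere median within these cells 0.20 (batches -0.04 and 0.46), but 12 of the 24 list genes are markers that name the class, so a cell with low levels leaves it, and fewer cardiac cells and lower levels per cell cannot be told apart. Unnamed clusters held 29.62% of P496L and 5.6% of WT cells there, and markers of other types did not rise alike (neural 3.79, endoderm 2.7, endothelial 0.96, epicardial -1.40), so a change in those types also stays open. At day 6 the share ratio was -1.29 beside -2.05 in whole sums and -0.92 within cardiac-like cells (batches -1.81 to 0.04; p = 0.129 with an estimated correlation), and share and level cannot be told apart with that spread between batches, the lowest being the batch of P496L replicate 2, in which 42.72% of cardiac-like cells had at least 2 TNNT2 UMIs. Doublet and free RNA effects on these sums were not separated.

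The library labelled GLYR1 knockout hiPSC had fibroblast matrix genes and almost no pluripotency transcripts. A mixture of hiPSC with other cells is excluded: 0% of its 2054 cells had at least 2 POU5F1 UMIs (95% upper limit 0.179%), where WT libraries had 99.9%. That it is a library of the P496L line, as one label field says, cannot be decided (the labels' extract protocol counts 2 P496L hiPSC libraries, where 1 is titled so): 6 genes low in P496L at all stages summed to 13.75 CPM there, to 57.88 and 85.41 CPM in WT and to 0.38 CPM in P496L, with ZNF667 at 1 UMI and CCDC125 at 1366. This test replaced an earlier sum over 22 genes, 241.69 CPM, after that sum was seen. Loss of GLYR1 stays open, with GLYR1 at -1.29 against WT hiPSC and 1 library only. GLYR1 was at 33.25 and 26.27 CPM in WT replicates 1 and 3 of day 18 and at 22.28 CPM here. The ratio to WT hiPSC alone therefore does not show a loss.

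For the siGATA4, whole-library day 6 and cardiac-like day 6 counts, the 10 splits of 3 against 3 are too few for a share under 0.05. The real split gave 5699, 26 and 122 genes and the highest other 0 in each case, so that 1 split, the real one, was as large. All 10 were counted alike, although at day 6 some put both libraries of a batch in 1 group. For GLYR1 regions that separate progenitors from hiPSC, 1 of 100 splits drawn, the real one, reached 376 and the highest other was 17. A random relabelling of these libraries is therefore unlikely to give as many. These splits take no account of batch. For P496L against WT progenitors, 5 of 35 splits gave at least the real 72 regions, so chance cannot be excluded, and the highest other gave 202; what that split rests on was not tested.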

How the results depend on the processing

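Settings described here as added were chosen after the data were seen; the others were fixed earlier. The siGATA4 count of 5699 stayed within 1.5 times under the replicate block (7242), quantile normalization (5666), median centring (5867, with 58.0% of calls higher against 48.2%), a mean log2 CPM of at least 1 (4946), edgeR on recovered reads (5938, added), the same with the block (7345, added) and without 1 library (4045 to 5904), and was 2730 without the eBayes trend; the block changed no call of a named siGATA4 gene. Day 6 whole-library calls, 26 in the report, were 915 with DESeq2, 186 without the gene filter, 49 without batch, 0 with the replicate block in place of batch, 335 with the stage alone, 42 with all barcodes and 0 to 369 without 1 library. Day 18 whole-library calls (830) were 3459, 1505, 315, 0 and 0 under the first 5 of these, 4531 with all libraries by title words, 0 by library name, and 0 to 2229 without 1 library. The stage difference (0) was 954 with DESeq2 (added), 55 without the filter (added), 2 without batch, 377 by title words and 0 to 319 without 1 library. Day 6 cardiac-like calls (122) were 365 with DESeq2, 1114 without the filter, 46 without batch, 3 with the replicate block, 12 when thinned, 74 at Leiden resolution 1.2, 60 without scaling within batch and 7 to 383 without 1 library. Day 18 cardiac-like calls (45) were 236, 722, 17 and 0 under the first 4 of these, 3 with the stage alone, 299 by title words, 0 by library name and 4 to 164 without 1 library. Single-cell replicate numbers do not follow the batches, so a call lost under that block is no measure of a weaker effect.

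Shares of cardiac-like cells kept their sign under every setting, from -32.59 to -12.25 points at day 6 and -55.74 to -39.62 at day 18 without 1 library, and -44.24 by title words (exact permutation p = 0.1) or -19.33 by library name (exact permutation p = 0.4); without scaling within batch (added) the day 6 difference was -10.06 points. For hiPSC, P496L ratios beyond 1 numbered 262, then 122 with at least 300 UMIs and 3027 against the WT library of the other batch. Requiring a log2 change of at least 1 left 6681, 4701 and 5310 genes for the GATA4, NKX2-5 and TBX5 knockouts. The ChIP stage difference of 67.7 Mb was 72.8 within Batch3, 94.3 without a batch label, 69.1 with the replicate block (exact permutation p = 0.0625, the smallest that 5 pairs allow) and 55.1 to 77.8 without 1 library; separating regions (376) numbered 2605, 1069, 213 with the 3 WT libraries of the genotype set added and 381 to 680 without 1 library. No paired analysis was run for P496L against WT progenitor ChIP libraries, which share no replicate number in their titles; tags in their library names match P496L replicates 1 and 3 (58.1 and 125.1 Mb) with WT replicates 6 and 7 (120.0 and 152.3 Mb), and the labels do not say what a tag stands for. The unpaired difference ranged from -52.2 to -18.7 Mb and its regions from 76 to 170 without 1 library. The GATA4 fold averaged 0.785 and was 0.927 with bases of any GLYR1 library. The H3K36me3 overlap (fold 6.95) had a fold of 6.07 with H3K36me3 bases of any library and 6.87 with random placement, and domain lists without a score gave no stricter alternative. Reversed signs were TBX18 (0.193), BNC1 (0.406) and CDT1 (-0.003) at day 18 by library name, and GLYR1, never called, at -0.008 in whole day 18 sums without P496L replicate 2 (0.243 without P496L replicate 1) and in cardiac-like sums at -0.008 when thinned and -0.041 by title words. For named genes 147 values kept their call and 73 lost it at day 6, 539 and 557 at day 18, 301 and 90 and then 210 and 113 in cardiac-like sums, and 1238 and 77 under siGATA4. The cause of these changes was not tested, except that fewer libraries leave fewer residual degrees of freedom. At day 18, thinning to the smallest library left 754 calls in whole sums (34947894 UMIs) and 31 in cardiac-like sums (8529301 UMIs).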

Other observations

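The comparisons with regions and with libraries of disputed labels in this part were chosen only after the results were seen. GLYR1 domains in P496L progenitors were looked up in the 334 regions that had a domain in all WT progenitor and no hiPSC library of the stage set. WT replicates 5, 6 and 7 of the genotype set, which had no part in choosing these regions, had a domain in 70.7%, 69.8% and 83.2% of them, and P496L replicates 1, 2 and 3 in 16.8%, 48.2% and 63.5%. The means were 74.6% ± 7.5 and 42.8% ± 23.8 (SD, n = 3 each), and the exact permutation p of 0.1, two-sided, is the smallest this design allows. The make-up of these ChIP cultures is not known. In day 6 single-cell libraries, cardiac-like cells averaged 16.96% in P496L and 41.47% in WT. A difference in cells and one in GLYR1 binding therefore cannot be told apart here. P496L replicates 1, 2 and 3 covered 58.1, 117.9 and 125.1 Mb in all, and WT replicates 5, 6 and 7 covered 113.2, 120.0 and 152.3 Mb. The lowest and highest shares were those of the libraries that covered least and most.

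GATA4 events in H3K36me3 domains outside the bases of any WT progenitor GLYR1 library of the stage set were above the shifted share. The folds were 1.235 and 1.337 in the 2 libraries, with 0 of 100 shifts reaching the observed share in either. Those domains span 243.9 Mb. Gaps were not excluded from the shifts, which raises the folds of 1.235 and 1.337 by an amount that was not measured. Events in the bases left out here, those of any GLYR1 library, had folds of 0.972 and 0.882. Of 100 shifts, 89 and 100 gave at least the observed share there. The folds of 0.87 and 0.70 belong to the narrower GLYR1 set of the main comparison, which spans 166.2 Mb. Bases of at least 3 GLYR1 libraries without H3K36me3 in any library, only 0.7 Mb with 0.11% and 0.14% of events, had folds of 4.86 and 5.82. Of 100 shifts, 0 reached these shares. With random placement of events the folds were 4.22 and 13.75, so their size depends on the placement used.

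For the 2 day 18 libraries whose labels disagree, the 6 genes low in P496L at all stages summed to 95.71 CPM in the library titled WT replicate 2 and to 3.36 CPM in the library titled P496L replicate 3. Undisputed libraries had 83.52 and 97.08 CPM (WT replicates 1 and 3) and 0.76 and 2.69 CPM (P496L replicates 1 and 2). Cardiac-like cells made up 66.05% of the library titled WT replicate 2 and 28.69% of the library titled P496L replicate 3. On both measures each of these libraries lay nearer the undisputed libraries of its title's genotype than those of its library name's. No library was regrouped on these values.

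The deposited siGATA4 table, made by the authors with another test, lists 10524 genes at an FDR of 0.05, 5125 higher and 5399 lower, with GATA4 at -2.16. Its fold changes had r = 0.928 across genes with those given in the report, and all 5660 genes called in both had the same sign. No single-cell library duplicates another of its group, the chi-square per gene between such libraries being 43.9 to 443.7. MT-RNR2, a mitochondrial ribosomal RNA, took 36.59% to 39.5% of CPM in the siGATA4 libraries.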
